A study of Arabidopsis thaliana with 8 samples.

How the data were processed

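Gene expression was measured in whole Arabidopsis thaliana seedlings with Affymetrix ATH1 arrays, which carry 22810 probe sets. There were 4 genotypes with 2 arrays each: wild type (Columbia), the T-DNA insertion mutants clf-28 and swn-7, and the clf-28 swn-7 double mutant. Per the labels' protocols, seeds were kept cold for 3 days and sown on nutrient plates at about 23 degrees Celsius and 70% humidity. Wild type and both single mutants grew for 10 days and the double mutant for 12 days. The labels give all 8 samples growth stage 1.03. Total RNA was extracted with a Qiagen kit and labelled with biotin. Genotypes and replicate numbers were taken from the labels. Nothing in the sources used here says whether the 2 arrays of a genotype came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

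The deposited values are array intensities, 1 signal per probe set and array on a linear scale. MAS5 and GCOS are named in the submitters' processing notes, and their versions are not given in the sources used here. The 2% trimmed mean of the signals was 100.0 on every array, so the signals were used as deposited, with no further scaling. Detection calls were not used here. The 27 control probe sets for transcripts that plants lack reached at most 8.74 on any array, below the floor described next. The number of arrays limits the precision of every value.

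Signals below a floor of 10.0, which is 10% of the mean trimmed mean, were set to the floor, and log2 was taken. The 64 control probe sets were left out. A probe set was tested if it lay above the floor on at least 2 arrays, which left 17332 of 22746. A linear model with 1 mean per genotype was fitted to all 8 arrays with limma 3.58.1 in R 4.3.3, with lmFit and eBayes and an intensity trend. It had 4 residual and 3.43 prior degrees of freedom. There were 6 contrasts: each single mutant against wild type, the double mutant against wild type and against each single mutant, and the interaction. The interaction is the log2 value of the double mutant minus both single mutants plus wild type, the departure from additive effects. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets tested and a threshold of 0.05. Errors of log2 changes are limma's standard errors (SE). A fold change against a genotype with 1 or both arrays at the floor is a lower bound, written as at least N-fold, and such bounds have no order. Interactions of genes at the floor in some genotypes depend on the floor.

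Genes were named from the platform's annotation, which gives 1 symbol for 13513 probe sets, several for 503 and does not list 8794. Names were updated through RefSeq gene tables, which matched 9492 of the 9532 tested probe sets with 1 symbol. Of the tested probe sets, 1335 belong to a gene with a symbol other than its locus. No genome build is given for the probes, so no coordinates are printed. The named genes follow a rule: for each contrast, up to 10 rises and 10 falls with the largest log2 change that passed the threshold with no overlap between the arrays compared, then the 3 members of each gene list with the smallest adjusted p. A gene with several probe sets takes the one with the highest mean. The model, the floor, the lists, this rule and all alternative settings were chosen before the data were examined.

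The 12 lists cover flowering time, embryo and seed maturation regulators, seed storage and oil body, photosynthesis, root markers, anther and pollen markers, stress and defence, reference transcripts, floral MADS-box genes, meristem and boundary genes, Polycomb machinery and cell cycle. Together they hold 166 entries, and few were named in the annotation used here. For floral MADS-box, meristem and boundary, Polycomb machinery and cell cycle genes 0 members were measured, and only photosynthesis and the reference transcripts had 3 or more. CLF and SWN are not named in the annotation used here, so the mutated genes were not analysed here as a check of the labels. Lists were tested with limma's camera (competitive, inter-gene correlation preset to 0.01, adjusted over 12 tests), and again with an estimated correlation, with fry and on ranks. After the values were seen, 52 families and 5 groups of genes picked by name were tested with camera, over 312 and 30 tests. The preset and the estimated correlation were both used. Most families were at least 5 genes that share the stem of their symbol. Plastid-encoded genes were taken by chromosome, and annotated pseudogenes by their annotated gene type.

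The alternatives were other floors, a constant added to the signal, quantile normalization, scaling to equal medians and other filters on dim or shared probe sets. Others were eBayes variants, the replicate number as a block, a 2-fold minimum, fits to the compared arrays alone and leaving out each array in turn. In the last, the genotype left with 1 array is assumed to vary like the others. Groups of 2 are too small for counts over regrouped arrays. The pipeline was tested on simulated data made from these arrays over 17332 probe sets. Noise was drawn independently for each probe set, and changes were placed only on probe sets with a mean more than 2-fold above the floor. For clf-28 against wild type it recovered 44% of 2-fold, 94% of 4-fold, 98% of 8-fold and 96% of 16-fold changes, 50 of each, with 18 false calls. For the double mutant against wild type it recovered 42%, 96%, 100.0% and 100.0%, with 11 false calls. In simulated data for that comparison, camera called 10 of 10 shifted sets and 1 of 30 unshifted sets, which does not cover sets of genes that vary together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.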

Results

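The transcriptomes of whole seedlings were compared between wild type and mutants that lack 1 or both of the related genes CURLY LEAF (clf-28) and SWINGER (swn-7), which encode histone methyltransferases of the Polycomb group. Each of the 4 genotypes was measured on 2 ATH1 arrays. Between 15710 and 16290 probe sets lay above the floor per array, or 69.1% to 71.6%. The first principal component carried 78.3% of the variance and separated both double-mutant arrays, at 135 and 122, from the other 6 arrays, at -47.4 to -39.8. The 2 arrays of a genotype correlated across probe sets at 0.986 for clf-28, 0.975 for swn-7 and 0.974 for the double mutant. The wild-type arrays correlated at 0.958, and 1059 of 17332 probe sets lay at least 2-fold apart between them, against 161 to 554 within the other genotypes. Probe sets are not independent replicates, so these correlations carry no p-value.

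**Figure D1:**
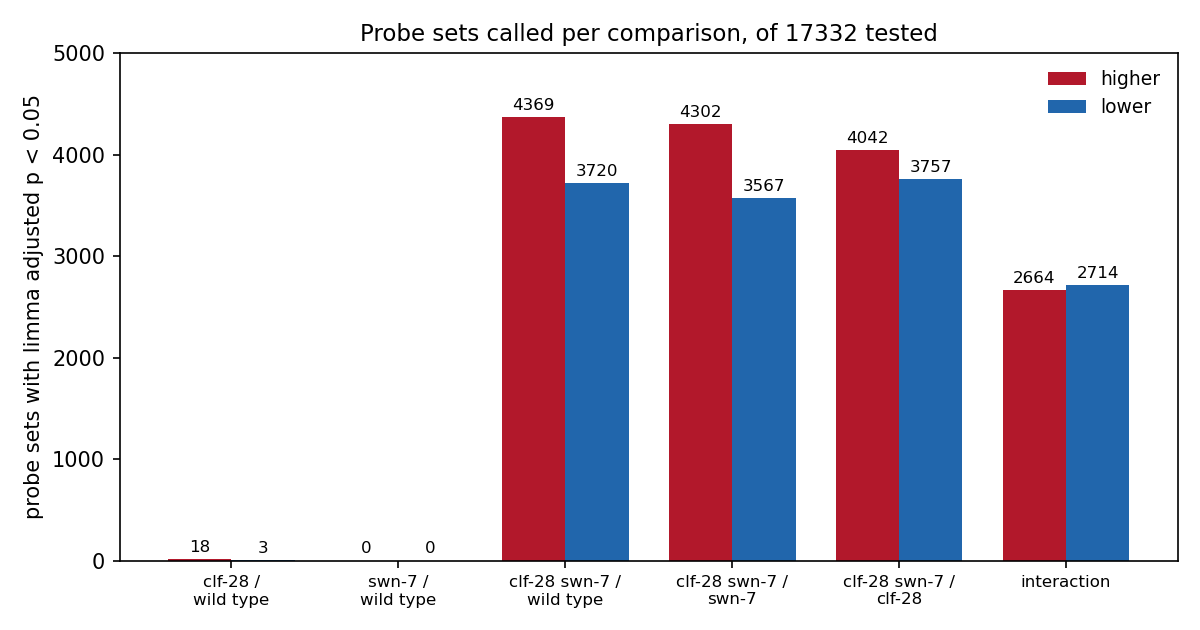
Bars give the number of probe sets that were higher (red) or lower (blue) with a limma adjusted p below 0.05 in each comparison, 2 arrays per genotype. The single mutants gave 21 and 0 calls, and each comparison of the double mutant gave 7799 to 8089.

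The comparison of clf-28 with wild type asks which transcripts change when CLF alone is lost. SWEET10, a member of a family of sugar transporters, was at least 15.0-fold higher in clf-28 (log2 3.91, SE 0.19, 2 arrays per genotype, limma adjusted p = 6.48e-04), with a mean signal of 151 and both wild-type arrays at the floor. AT1G09500 rose 10.7-fold (log2 3.42, SE 0.21, limma adjusted p = 0.00275) and AT3G19550 rose 9.30-fold (log2 3.22, SE 0.21, limma adjusted p = 0.00287). AT5G39520 rose 9.04-fold, AT5G39220 rose 6.70-fold, AT1G03710 was at least 5.61-fold higher, and AT4G01390 was 4.07-fold lower (log2 -2.02, SE 0.23, limma adjusted p = 0.0371). Both clf-28 arrays lay above, or for AT4G01390 below, both wild-type arrays. These 7 were the named genes among 21 called probe sets, 18 higher and 3 lower, all at least 2-fold. An unadjusted p below 0.05 was reached by 2162 probe sets.

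Among the flowering-time genes, the MADS-box genes AGL24 (log2 0.70, SE 0.24) and AGL19 (log2 0.61, SE 0.16) did not pass over all probe sets in clf-28 (limma adjusted p = 0.334 and 0.258), while 2 of 2 passed adjusted over the list alone. The seed protein genes OLEO3 (log2 -0.90, at the floor in clf-28) and PAP85 (log2 -0.92) gave 0 calls over all probe sets and 1 of 2 adjusted over the list alone. The same counts held for the stress list, in which COR15A had a log2 change of -1.22 (SE 0.39, limma adjusted p = 0.306) and PDF1.2 one of -0.15. BBM was at the floor in both genotypes, and EXPA7 (log2 0.71) and EMS1 (log2 0.01) did not pass, also adjusted over the list alone. Only 2 of 12 flowering-time, 2 of 14 seed storage and 2 of 14 stress members were measured. A pass over such a list alone is close to an unadjusted limma p below 0.05, which 2162 of 17332 probe sets reached. The 4 measured photosynthesis genes had a median log2 change of -0.29 (camera adjusted p = 0.252) and the 3 reference transcripts one of 0.08 (camera adjusted p = 0.804).

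The clf-28 calls, and their split into higher and lower, depended on the arrays and settings used. The split was 14 higher and 9 lower with no floor, and 29 and 13 with a constant added. Lower calls outnumbered higher ones when either wild-type array was left out. The count was 8 without clf-28 replicate 1, 2 without clf-28 replicate 2, 7 without either swn-7 replicate, and 584 without wild type replicate 2. It was 42 with a constant added to the signal in place of the floor and 0 when only the wild-type and clf-28 arrays were fitted, which leaves 2 residual degrees of freedom. SWEET10 passed in all 8 omissions of 1 array (limma adjusted p 0.00525 to 0.0208), but not with no floor (limma adjusted p = 0.0569) or with only the compared arrays (limma adjusted p = 0.219). AT1G09500 and AT3G19550 lost the call without clf-28 replicate 2 (limma adjusted p = 0.0717 and 0.0706), and AT1G03710 lost it without clf-28 replicate 1 or 2 (limma adjusted p = 0.0502 and 0.0797). AT5G39520, AT5G39220 and AT4G01390 passed in 1 of the 8 omissions, that of wild type replicate 2. Their limma adjusted p over the 8 omissions reached 0.297, 0.159 and 0.328.

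**Figure D2:**
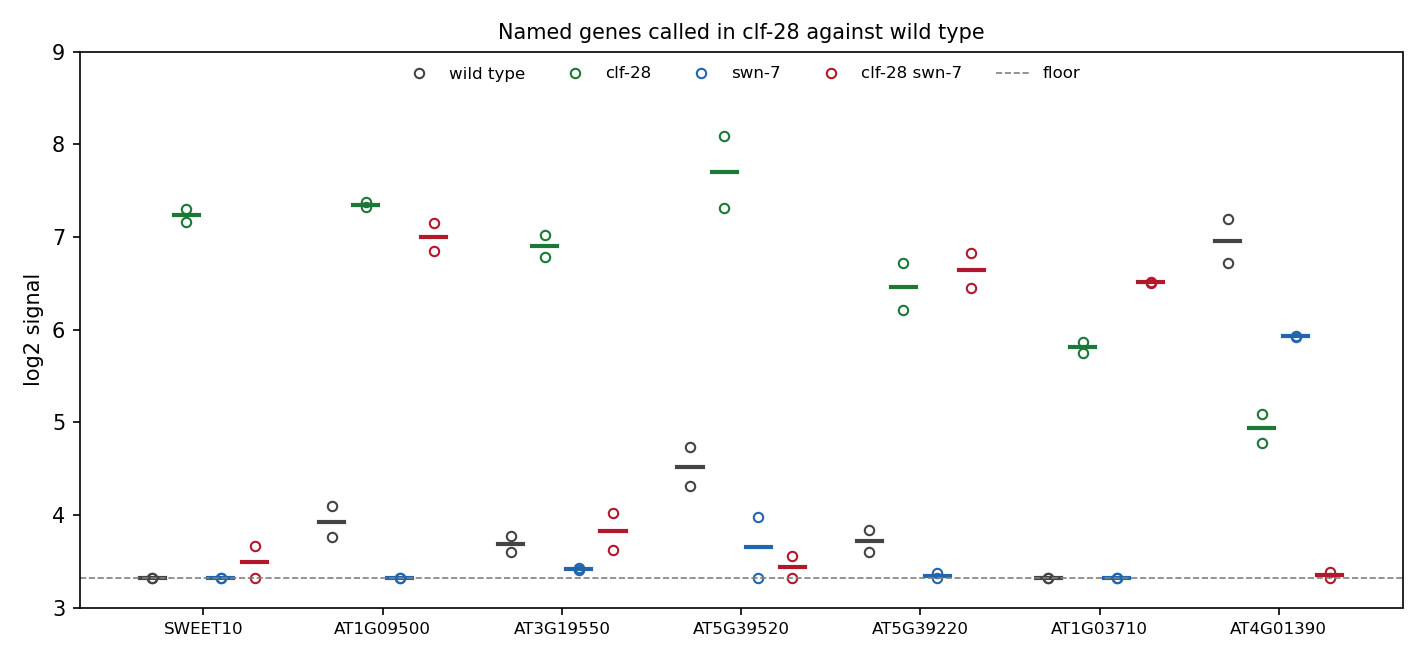
Each circle is the log2 signal of 1 array, short bars are the means of 2 arrays per genotype, and the dashed line is the floor (log2 3.32). SWEET10 lies above the floor on both clf-28 arrays (mean 7.23) and at it on both wild-type arrays, while AT1G09500 is also high in the double mutant (mean 7.00).

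The comparison of swn-7 with wild type asks the same for SWN alone. No named gene passed. The nearest was AT3G53250, at least 5.28-fold higher in swn-7 (log2 2.40, SE 0.23) with both wild-type arrays at the floor and a limma adjusted p of 0.0976. It passed without wild type replicate 2 (limma adjusted p = 0.0155) and at a floor of 20% (limma adjusted p = 0.0256). The flowering-time genes AGL24 (log2 -0.44) and AGL19 (log2 -0.08) and the photosynthesis genes (median log2 -0.06, camera adjusted p = 0.915) did not pass. PAP85 (log2 -1.73, SE 0.46) and OLEO3 (log2 -0.90, SE 0.29), both at the floor in swn-7, did not pass over all probe sets, and 2 of 2 passed adjusted over the list alone. With 2 members, that is close to an unadjusted limma p below 0.05, which 2117 probe sets reached in swn-7. PAP85 and OLEO3 were both higher on wild type replicate 2 (log2 5.86 and 4.68) than on wild type replicate 1 (log2 4.25 and 3.77). Their falls in swn-7 and in clf-28 therefore rest in part on wild type replicate 2. AT1G47540, AT2G15010 and AT2G28490, picked after their values were seen, lay above the floor on wild type replicate 2 and at it on wild type replicate 1. BBM (log2 0), EXPA7 (log2 -0.32), EMS1 (log2 -0.28), COR15A (log2 -0.17), PDF1.2 (log2 0.64) and the reference transcripts (median log2 0.17, camera adjusted p = 0.804) did not pass in either way.

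The 69 probe sets of plastid-encoded transcripts, a family formed after the values were seen, had a median log2 change of -1.49 in swn-7 (camera adjusted p = 4.00e-09; adjusted p = 0.947 with an estimated correlation), which kept its sign under both other scalings. Of these 69, 0 passed alone. The median rested on 1 array: against the wild-type mean it was -2.90 for swn-7 replicate 2 and -0.03 for swn-7 replicate 1. In clf-28 the median was -0.62 (camera adjusted p = 0.00323; adjusted p = 0.949 with an estimated correlation). In swn-7, limma called 0 of 17332 probe sets, and 2117 had an unadjusted p below 0.05. Of the other limma settings, a floor of 20% and no floor gave 2 calls each, leaving out wild type replicate 1 gave 15 and leaving out wild type replicate 2 gave 806.

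**Figure D3:**
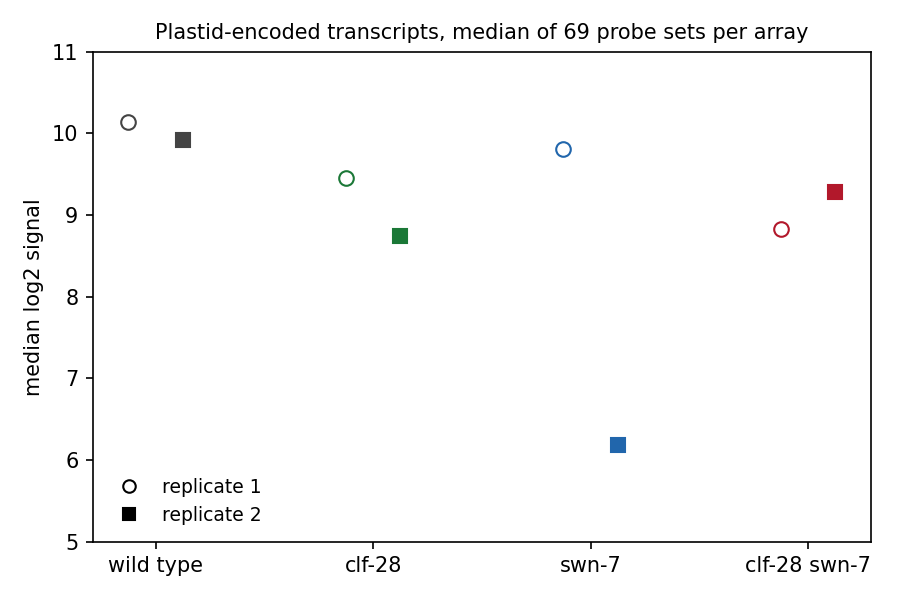
Symbols give, for each array, the median log2 signal of the 69 plastid-encoded probe sets by genotype, with open circles for replicate 1 and filled squares for replicate 2. The value of swn-7 replicate 2, 6.19, lies below the other 7 arrays, at 8.74 to 10.1.

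The largest named rises of the double mutant over wild type included LEA18 and AtLEA4-1, which encode late embryogenesis abundant proteins. They were at least 474-fold and at least 268-fold higher (log2 8.89 and 8.07, SE 0.18 and 0.18, 2 arrays per genotype, limma adjusted p = 6.96e-07 for both). ICL, which encodes the glyoxylate-cycle enzyme isocitrate lyase, was at least 390-fold higher (log2 8.61, SE 0.37, limma adjusted p = 4.56e-06), with 1 of 2 wild-type arrays above the floor. The seed storage and oil body list rose in 2 of 2 measured members: OLEO3, which encodes an oil-body oleosin, rose 113-fold (log2 6.82, SE 0.29) and PAP85, which encodes a vicilin-like storage protein, rose 121-fold (log2 6.92, SE 0.46). The PAP85 value was 6.11 without wild type replicate 1 and 7.72 without wild type replicate 2. With 2 of 14 and 1 of 12 members measured, the seed storage and embryo regulator lists were not tested as sets. BBM, which encodes a transcription factor that promotes embryo formation, was the 1 measured embryo regulator. It was at least 6.04-fold higher (log2 2.59, SE 0.16, limma adjusted p = 2.43e-05) and at the floor on the other 6 arrays.

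The measured photosynthesis genes fell together. Of the 28 members of the list 4 were measured, and all 4 passed, with a median log2 change of -3.82 (camera adjusted p = 4.48e-04, and 0.267 with an estimated correlation). LHCB4.1, a light-harvesting antenna protein, was 15.9-fold lower (log2 -3.995, SE 0.25). The Calvin-cycle enzymes PRK and SBPASE were 15.5-fold (log2 -3.96, SE 0.26) and 12.4-fold lower (log2 -3.64, SE 0.28), with limma adjusted p values of 2.12e-05, 3.00e-05 and 5.69e-05. ECS1 fell 112-fold (log2 -6.81, SE 0.22), from a mean signal of 2975 to 27.0. AT1G29660 was at least 82.1-fold lower (log2 -6.36, SE 0.22). AT1G66100 fell at least 65.3-fold (log2 -6.03, SE 0.28) and LrgB at least 50.3-fold (log2 -5.65, SE 0.26), each with 1 of 2 double-mutant arrays above the floor.

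**Figure D4:**
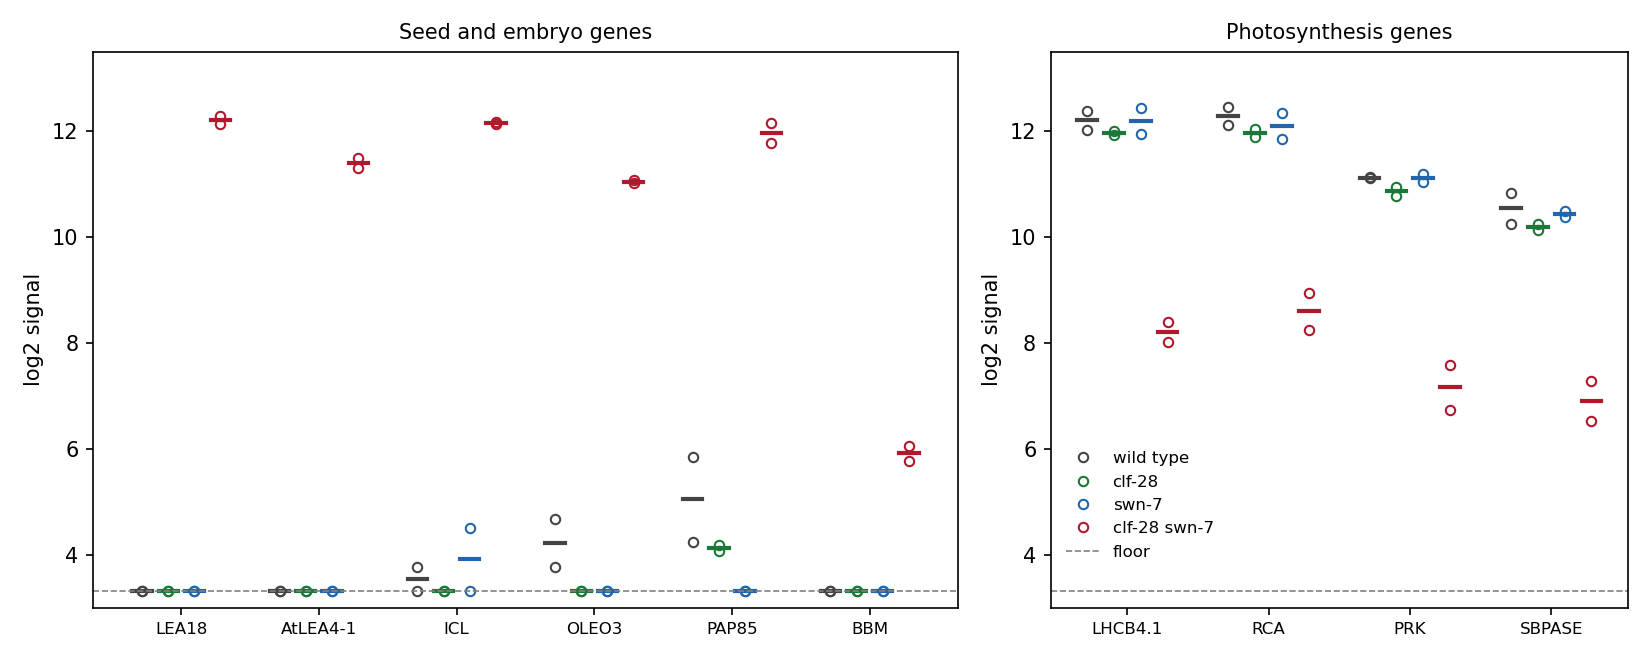
Each circle is the log2 signal of 1 array, short bars are the means of 2 arrays per genotype, and the dashed line is the floor (log2 3.32). All 6 seed and embryo genes are higher, and all 4 photosynthesis genes lower, on both double-mutant arrays than on the other 6 arrays.

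The remaining lists changed in part. AGL24, a MADS-box gene that promotes flowering, rose 4.82-fold (log2 2.27, SE 0.24, limma adjusted p = 2.86e-04), and AGL19 did not pass (log2 0.08, SE 0.16), so 1 of 2 passed both over all probe sets and adjusted over the list alone. COR15A, a cold-regulated gene, fell 7.83-fold (log2 -2.97, SE 0.39, limma adjusted p = 7.33e-04), with -2.38 without double-mutant replicate 1 and -3.56 without double-mutant replicate 2, and the defensin gene PDF1.2 did not pass (log2 0.02, SE 0.28). EXPA7, an expansin gene of root hairs, was at least 2.30-fold lower (log2 -1.20, SE 0.39, limma adjusted p = 0.0395). That call was lost at a floor of 20% (limma adjusted p = 0.530) and without any 1 of the 6 wild-type, clf-28 and double-mutant arrays (limma adjusted p 0.0565 to 0.194). The anther gene EMS1 (log2 -0.59, SE 0.21, limma adjusted p = 0.0542) was the 1 measured member of 8 in its list. Its pass over the list alone is therefore an unadjusted limma p below 0.05, which 9436 of 17332 probe sets reached here. EMS1 lay close to the floor on both double-mutant arrays (log2 3.34 and 3.38). Over all probe sets it passed without clf-28 replicate 1 or 2 (limma adjusted p = 0.0235 and 0.0256), with no filter (limma adjusted p = 0.0484) and with only the compared arrays (limma adjusted p = 0.0254). Of the reference transcripts, AT4G34270 was higher (log2 0.58, SE 0.18, limma adjusted p = 0.0308), a call lost without any 1 of the same 6 arrays (limma adjusted p 0.0510 to 0.120) and with only the compared arrays (limma adjusted p = 0.0733). PEX4 (log2 -0.24) and AT2G28390 (log2 0.19) did not pass (camera adjusted p = 0.915 for the list).

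Families that share the stem of a symbol were formed after the values were seen. Of 5 measured LEA genes 4 rose, LEA4-5 by log2 7.97 (SE 0.30, 1 of 2 wild-type arrays above the floor) besides those above, with a camera adjusted p of 0.0266 (adjusted p = 0.947 with an estimated correlation). Of 18 measured TBL genes, a family of wall polysaccharide acetylation, 6 fell and 0 rose, led by TBL45 (log2 -4.62, SE 0.30) and TBL25 (log2 -2.001, SE 0.22), with a camera adjusted p of 0.0450 (adjusted p = 0.947 with an estimated correlation). The CRR genes of the plastid NADH dehydrogenase-like complex fell in 5 of 7 cases, among them NdhL (log2 -4.60, SE 0.23) and CRR42 (log2 -2.61, SE 0.28), with a camera adjusted p of 0.0590. The SWEET sugar transporters moved both ways, 5 higher and 6 lower of 13 (camera adjusted p = 0.834). SWEET11 (log2 -5.21, SE 0.13) and SWEET2 (log2 -3.05, SE 0.22) fell, and SWEET1 (log2 2.01, SE 0.17) and AtVEX1 (log2 2.04, SE 0.26) rose. The LEA, TBL and CRR medians kept their sign under both other scalings.

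Limma called 8089 of 17332 probe sets (46.7%) in the double mutant against wild type, 4369 higher and 3720 lower (3859 and 3894 with arrays scaled to equal medians). At least 2-fold changes numbered 4959, and at least 8-fold changes 680, with 306 higher and 374 lower. Of the probe sets, 426 lay above the floor on both double-mutant arrays and on none of the other 6 arrays, and 445 showed the opposite. The double mutant was grown 2 days longer than the other genotypes, so genotype and age cannot be told apart in any of its comparisons.

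Against swn-7, the double mutant asks what the loss of CLF adds when SWN is missing. AT1G47540 was at least 496-fold higher (log2 8.95, SE 0.50, limma adjusted p = 1.31e-05) and PAP85 at least 400.1-fold higher (log2 8.64, SE 0.46). AGL24 rose 6.51-fold (log2 2.70, SE 0.24, limma adjusted p = 1.19e-04). AT5G62280 was at least 52.9-fold lower (log2 -5.73, SE 0.42) and the cold-regulated gene COR15B fell at least 51.1-fold (log2 -5.67, SE 0.35), with 1 of 2 double-mutant arrays above the floor. Limma called 7869 probe sets, 4302 higher and 3567 lower, so 54.7% were higher. With arrays scaled to equal medians, 3335 were higher and 4147 lower (44.6% higher). That scaling moved the median log2 change of all tested probe sets from 0.13 to 0, and in the interaction from 0.12 to -0.04, so the split between higher and lower is relative to it.

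Against clf-28, the double mutant asks what the loss of SWN adds when CLF is missing. AT3G01570 was at least 397-fold higher (log2 8.63, SE 0.64, limma adjusted p = 5.79e-05), AGL24 rose 2.97-fold (log2 1.57, SE 0.24, limma adjusted p = 0.00178) and AT2G33850 fell at least 51.5-fold (log2 -5.69, SE 0.20), with 1 of 2 double-mutant arrays above the floor. EXPA7 was at least 3.76-fold lower (log2 -1.91, SE 0.39, limma adjusted p = 0.00635). It lost the call without clf-28 replicate 2 (limma adjusted p = 0.0544) and without double-mutant replicate 1 or 2 (limma adjusted p = 0.0789 and 0.0701). AGL19 was lower (log2 -0.52, SE 0.16, limma adjusted p = 0.0341), and passed in 3 of 8 omissions of 1 array, those of either wild-type array and of double-mutant replicate 1 (limma adjusted p 0.0154 to 0.140 over all 8). It also lost the call at a floor of 5% (limma adjusted p = 0.164), with no floor (limma adjusted p = 0.222), with a constant added (limma adjusted p = 0.157), with robust eBayes (limma adjusted p = 0.0509) and with only the compared arrays (limma adjusted p = 0.0597). Limma called 7799 probe sets, 4042 higher and 3757 lower (3568 and 3950 with arrays scaled to equal medians). The count was 5024 without clf-28 replicate 1, 4997 without clf-28 replicate 2 and 5156 without double-mutant replicate 1.

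The interaction tests whether the double mutant departs from the sum of both single-mutant effects. The photosynthesis genes lay below that sum in 4 of 4 cases, with a median interaction of -3.44 (camera adjusted p = 4.48e-04; adjusted p = 0.267 with an estimated correlation), including LHCB4.1 (log2 -3.74, SE 0.35, limma adjusted p = 3.26e-04). LEA18 had an interaction of 8.89 (SE 0.25, limma adjusted p = 8.11e-06), equal to its change from wild type because it was at the floor in wild type and both single mutants. PAP85 (log2 9.57, SE 0.65), OLEO3 (log2 8.62, SE 0.42), BBM (log2 2.59, SE 0.23) and AGL24 (log2 2.01, SE 0.34) were also positive. The PAP85 value was 10.37 without wild type replicate 1 and 8.76 without wild type replicate 2. AT3G62550 was negative (log2 -7.47, SE 0.83, limma adjusted p = 7.18e-04). Its value was -6.82 and -8.13 without wild type replicate 1 and 2, and -6.59 and -8.36 without double-mutant replicate 1 and 2. COR15A did not pass (log2 -1.59, SE 0.55, limma adjusted p = 0.0629), but did without double-mutant replicate 2 (limma adjusted p = 0.0344), and narrowly at a floor of 5%, with no floor, with a constant added and with robust eBayes (limma adjusted p 0.0410 to 0.0499). Limma called 5378 probe sets, 2664 positive and 2714 negative (2099 and 3097 with arrays scaled to equal medians). The count was 3395 without clf-28 replicate 1, 3274 without clf-28 replicate 2 and 3556 without double-mutant replicate 1.

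The effect of clf-28 was then set beside its effect in plants that lack SWN, 2 comparisons that share no array. SWEET10 rose in clf-28 but had a mean signal of 7.51 in the double mutant, with 1 of 2 arrays above the floor, and an interaction of -3.74 (SE 0.27, limma adjusted p = 9.95e-05). AT3G19550 (log2 -2.81, limma adjusted p = 5.89e-04) and AT5G39520 (log2 -3.38, limma adjusted p = 0.00210) also had negative interactions, whereas AT1G09500 and AT5G39220 had mean signals of 129 and 101 in the double mutant. These genes were picked for their change in clf-28, which enters the interaction with a minus sign, so the picking favours negative interactions. Of the 18 probe sets higher in clf-28, 8 were also higher in the double mutant against swn-7, where 4.47 would be shared by independent lists, 2 were lower and 8 were not called. Of the 3 lower in clf-28, 2 were also lower, where 0.617 would be shared, and 1 was higher. Across all 17332 probe sets the log2 changes of the 2 comparisons correlated at r = -0.0365 (Spearman's rho 0.00349), with r between -0.0911 and 0.0609 over the 16 choices of 1 array per genotype and r = 0.0190 without wild type replicate 1. For swn-7 against wild type and the double mutant against clf-28, r was -0.132 (rho -0.0737), -0.110 without swn-7 replicate 1, and between -0.130 and -0.0492 over the 16 choices of 1 array per genotype.

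The 2 single-mutant comparisons share the wild-type arrays. Their log2 changes correlated at r = 0.669 across probe sets, and groups without effects simulated against the same arrays gave 0.679. The covariance was 0.127 against 0.0719 in the simulation. A split of the wild-type arrays would leave 1 in each part and was not made, so part of the excess may come from those arrays.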

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

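Of the tests in this part, the interaction and the scalings were planned, and the tests on labelled RNA and on plant age were chosen after the results were seen.

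The double mutant departed from the sum of both single-mutant changes, which the interaction tested directly: 5378 of 17332 probe sets passed in limma, with plant age confounded in it as in every comparison of the double mutant. The median interaction of the 4 photosynthesis genes was -3.44 in log2. Of the 21 probe sets called in clf-28, 13 also had an interaction, but the clf-28 change enters the interaction with a minus sign on the same arrays, so the picking raises this count and it is no evidence by itself. Against swn-7, a comparison that shares no array, 8 of the 18 probe sets higher in clf-28 were higher in the double mutant, 2 were lower and 8 were not called. In data outside the main measurement, the control probe set for 5S ribosomal RNA had a mean signal of 144 ± 87.6 (SD, n = 2) in the double mutant and 33.7 ± 3.51 (SD, n = 2) in wild type.

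In the double mutant 8089 probe sets changed against wild type. The choice among these scalings of the arrays is argued against, since the smaller count under quantile normalization and equal medians was 7753. The array medians were already close (36.2 to 42.9), so equal medians was a mild change. The spike-in controls of the double mutant lay 0.76 log2 units above those of the single mutants. The change predicted from the spike-in level within the other genotypes had a slope of 0.0112 on the change observed, over 6641 probe sets called against both single mutants. That relation rests on few arrays, above all the wild-type pair, which differed most in spike-in level (log2 8.13 and 7.29). The slope argues only against an effect of labelled RNA that also shows between arrays of the same genotype. The 2 days of extra growth remain open and cannot be told apart from genotype, as 0 double-mutant arrays came from plants grown for 10 days. The loss of both genes is the biological explanation that the design names, and it remains a hypothesis beside plant age.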

How the results depend on the processing

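All alternatives were planned. The count for clf-28 against wild type (21) was 42 with a constant added to the signal, 0 with only the arrays compared and 2 to 584 without 1 array. With wild type replicate 1 left out it was 22, of which 9 were among the 21. The count for swn-7 (0) was 2 at a floor of 20%, 2 with no floor and 0 to 806 without 1 array. With a 2-fold minimum the double mutant gave 4959 calls against wild type, 4855 against swn-7 and 4768 against clf-28. Without 1 array the count against clf-28 was 4997 to 8302 and the interaction 3274 to 5678. The relation of the clf-28 effects was -0.0812 with no floor and -0.0651 to 0.0190 without 1 array; that of the swn-7 effects was -0.193 with no floor and -0.148 to -0.110 without 1 array. The causes were not tested. Other counts stayed within 1.5 times, from 5499 to 8314 for the double mutant against wild type. With the replicate number as a replicate block the counts were 23, 0, 7970, 7817, 7761 and 5272, AT4G01390 lost its call in clf-28 (limma adjusted p = 0.0719) and EMS1 gained one in the double mutant (limma adjusted p = 0.0466). The deviations of same-numbered arrays correlated at -0.0775 to 0.222, which does not settle whether the numbers pair the samples. The array median of 12 transcripts taken as mitochondrion-encoded, for example, was lower on replicate 2 in all 4 genotypes. For the 87 values of named genes, 1726 of 1805 alternatives kept the side of the threshold, 67 lost the call, 12 gained it and 0 turned sign past it. Values that stayed short of the threshold were not checked for direction, and some turned sign. AGL19 in the double mutant against wild type ranged from log2 -0.0759 to 0.238 without 1 array. The list tests kept their side of the threshold in 258 of 262, and the 4 exceptions were the photosynthesis list with an estimated correlation (adjusted p = 0.267). Signals near the floor of 10.0 limit what can be said of dim genes, since folds against the floor are lower bounds.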

Other observations

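All tests in this part were chosen after the results were seen, except the scalings in the paragraph on the wild-type arrays, which were planned.

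Groups picked by gene name extended the picture of the double mutant. Of 10 nuclear genes for photosystem, light-harvesting and NADH dehydrogenase-like subunits, 9 fell against wild type, with a median log2 change of -4.03 (camera adjusted p = 8.18e-06; adjusted p = 0.325 with an estimated correlation). LHCB4.2 (log2 -5.19, SE 0.25), PSAN (log2 -4.36, SE 0.26) and PSAE-1 (log2 -4.06, SE 0.31) were among them, and LHCB4.3 rose (log2 2.24, SE 0.28). LHCB4.1 also belongs to the photosynthesis list and NdhL to the CRR genes above. The group is therefore not independent of those results. Of 9 genes for enzymes of tetrapyrrole and chlorophyll synthesis 6 fell and 0 rose, among them CHLI2 (log2 -3.25, SE 0.33), PORB (log2 -2.9996, SE 0.26) and HEMB1 (log2 -1.69, SE 0.17), with a camera adjusted p of 0.00452 (adjusted p = 0.339 with an estimated correlation).

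Of 4 genes for vacuolar processing enzymes, proteases that mature seed storage proteins among other targets, BETA-VPE (log2 5.62, SE 0.29) and DELTA-VPE (log2 5.94, SE 0.32) were among 3 that rose, and GAMMA-VPE fell (log2 -1.27, SE 0.16), with a camera adjusted p of 0.0983. Of 4 cold-regulated COR genes, COR15B (log2 -5.13, SE 0.35) and COR47 (log2 -3.49, SE 0.29) were among 3 that fell, and COR27 rose (log2 1.504, SE 0.26), with a camera adjusted p of 0.0709. Of 12 genes taken as mitochondrion-encoded from their symbols alone (nad, cox and ccb), which the gene tables did not match, 5 rose and 0 fell, nad9 by log2 1.97 (SE 0.25), with a median of 1.11 (camera adjusted p = 0.0176; adjusted p = 0.451 with an estimated correlation). The same group was lower than wild type in clf-28 (median -0.54, camera adjusted p = 0.00452; adjusted p = 0.400 with an estimated correlation) and swn-7 (median -0.64, camera adjusted p = 0.00362; adjusted p = 0.395 with an estimated correlation), with 0 of 12 called in either. The swn-7 fall rested mostly on swn-7 replicate 2: the array medians were 4.71 and 3.70 for swn-7 replicates 1 and 2, against 5.25 and 4.70 in wild type. Each lay below the wild-type array of the same number. The medians of all 5 groups in the double mutant against wild type kept their sign under both other scalings.

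Wild type replicate 1 stood apart from wild type replicate 2. Of the 1059 probe sets at least 2-fold apart, 340 were higher on replicate 2 and 719 on replicate 1, among the latter CML38 (signals 141 and 13.7), GTR1 (1034 and 134), XTH18 (391 and 61.8) and STZ (201 and 36.3). Only the choice among these scalings is argued against, with 1029 such probe sets as the smaller count under the other scalings. The medians of the wild-type arrays were already close, so equal medians was a mild change. The amount of labelled RNA stays open, although the slope between predicted and observed differences was -0.0216. That prediction rests on few arrays. Among the other genotypes the swn-7 pair differed most in spike-in level (log2 7.54 and 6.93), less than the wild-type pair (log2 8.13 and 7.29). The correlations argue against replicate 1 being an array of a mutant genotype. With the mutant arrays they were 0.700 to 0.948, below its 0.958 with replicate 2. They also lay below the 0.974 to 0.986 between the 2 arrays of each mutant genotype. A swap of replicate 2 with an array of another genotype stays open: replicate 2 correlated with the 4 single-mutant arrays at 0.967 to 0.980, above its 0.958 with replicate 1. RNA quality, and how these plants were grown, handled or harvested, remain open and were not tested: replicate 1 had the highest actin 3'/5' signal ratio of the 8 arrays (3.21, others 1.58 to 2.83) and the lowest 25S ribosomal RNA signal (63.8, others 146 to 3350), while its GAPDH 3'/5' ratio of 0.897 lay within the others' range of 0.831 to 1.22.

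Plastid-encoded transcripts were lower in swn-7 on 1 array. Their median difference from the wild-type mean was -0.0263 on swn-7 replicate 1, against 0.43 between the wild-type arrays, and -2.90 on swn-7 replicate 2, where 68 of 69 probe sets lay below that mean. This fits a property of that 1 array better than one of the genotype. A lower yield of organelle RNA on it stays open: the 12 probe sets taken as mitochondrion-encoded had a median difference of -0.537 between its value and that of replicate 1, with 10 of 12 lower, but their array median was also lower on replicate 2 than on replicate 1 in wild type (4.70 and 5.25), clf-28 (3.81 and 4.31) and the double mutant (5.78 and 6.47). No biological explanation was tested.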
